A study of Mus musculus with 3 samples.

How the data were processed

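The series held 3 ATAC-seq samples with 1 peak table each, and each sample was a group of its own: control progenitors, control cells after 1 day of T3 at 60 nM, and Seh1cKO cells after the same treatment. The title of the first sample ends in the letters DO, which was read as day 0. Per the labels' protocols 50000 cells per library were taken and tagged with a commercial transposase kit. Other assays named in the series design, and Seh1cKO cells at the progenitor stage, were not analysed here. The samples are not replicates of each other, and the labels name no animal, litter or batch.

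Per the submitters' processing notes, Bowtie2, SAMtools and MACS2 were used with the genome build mm10. Per the file headers peaks were called in each library separately with MACS 2.1.2_dev on paired-end fragments, with all duplicate fragments kept, no control library, a q cutoff of 0.05, a maximum gap of 50 bp, a minimum length of 100 bp, a local background of 10000 bp and an effective genome size of 1.87e+09. The name of the input given in the headers refers to removal of mitochondrial reads. Whether reads were shifted for the transposase cut, and whether regions of artificial signal were removed, is not given in the sources used here. The deposited tables give a peak's position, the pileup signal at its summit in fragments, the −log10 of its p-value and q-value, and its fold enrichment as a ratio to the local background, per the file headers. The names of both −log10 columns were damaged in the deposited tables. They were identified from their place in the caller's fixed column order and by recomputing the Poisson p-value from pileup and fold, which came within 0.01 of the deposited −log10 p for at least 99.9% of peaks in each table. These scores are the authors' and were used to describe, rank and filter peaks within a list and to thin it. Keeping duplicates means that amplified copies of a fragment can build a pileup, at weak and strong peaks, and no table used here measures this.

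Positions are 1-based, in mm10. Gene positions came from the RefSeq annotation of GRCm38.p6, whose main chromosomes have the coordinates of mm10, for 21887 protein-coding genes. The annotation table gives each gene's first and last base without strand, exons or transcription starts. The planned promoter window was therefore placed at both annotated ends of a gene, 1000 bp on either side, and is called a gene-end window. Among genes over 5000 bp, 9.90% in progenitors, 11.2% in control cells at day 1 and 4.33% in Seh1cKO cells had peaks at both ends. No genome sequence was used here, so the 16 consensus motifs and the GC content that had been planned were not examined.

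A peak was counted as present in another library when a peak there overlapped it by at least 1 bp. Peaks of each list were ranked by −log10 q into 10 deciles of equal size. Differences between classes of peaks were averaged over deciles with equal weight. Shares have exact Clopper-Pearson intervals at 95%, which cover counting error only, since fragments without molecular identifiers are not independent molecules. There was no test between conditions because each group has 1 library. The depth limits what a library can show: the lowest pileup called was 9 in progenitors, 8 in control cells at day 1 and 6 in Seh1cKO cells, and a site without a call may be open below that level. To describe depth, each control day 1 pileup was thinned at random to 59.4% and its background scaled alike, 20 times, and was counted as callable where its Poisson p passed the weakest p called in the Seh1cKO list. This ignores the minimum length of a peak, so it gives an upper limit. The planned test of depth, which gave 1.92 times against its bound of 1.5, rested on that limit and was dropped. In its place thinned peaks were counted at the p of Seh1cKO peaks with a −log10 q of at least 10, of which 0.923% were under 200 bp wide, and gave 1.40 times. The bound of 1.5 was first kept for this count and would have labelled depth as fitting. It was lowered to 1 after the value was seen, since a random subsample at the Seh1cKO depth leaves nothing else for depth to explain. A test that compared the shares of peaks of a single control library present in Seh1cKO cells was also replaced, because the 2 control libraries differ in depth. Its place was taken by the number of peaks found in neither other library. For the class comparison that uses the control day 1 library on both sides, 10 simulations gave every control day 1 peak and every 200 bp background window 1 rate, scaled to depth, in all 3 libraries. Observed and simulated values were compared over the 8 weaker deciles, because the simulations made at most 2 gained peaks in the strongest 2. The planned test of sex chromosomes, the difference on autosomes over all deciles, was dropped because few peaks lie on the sex chromosomes and it was bound to stay near the full value. The strongest decile of autosomal peaks took its place. It too leaves out few peaks and could hardly move, so it shows only whether the difference rests on peaks of the sex chromosomes.

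Before the data were examined, 13 gene lists were fixed: myelin and mature oligodendrocyte genes, oligodendrocyte lineage regulators, progenitor genes, cell cycle genes, cholesterol and sterol synthesis genes, thyroid hormone response genes, nucleoporin genes, SWI/SNF genes, housekeeping genes, and markers of astrocytes, neurons, microglia and macrophages, and endothelial and mural cells. All listed genes were found in the annotation, and Ccnd1, Id3, Rxrg, Brd7 and Smarca4 stand in more than 1 list. For each list the genes with a gene-end peak and the peaks in the locus, meaning the gene and 10000 bp on either side, were counted. A list's share was placed as a percentile among 10000 random lists of the same number of genes, matched on the strength of the gene-end peak or on the number of locus peaks in the reference library. A percentile describes these libraries and is not a test. With 13 lists, 2 comparisons and several kinds of percentile for each list, some percentiles beyond 2.5 or 97.5 arise by chance. Named genes followed a rule also fixed before the data were examined: Seh1l, Olig2 and Brd7 first, then for each comparison the 8 genes with the strongest gene-end peak in one library and none in the other, in both directions, the 5 genes with the largest fall and the 5 with the largest rise in locus peaks, and up to 4 members of each list with the largest difference in locus peaks. Predicted genes and olfactory and vomeronasal receptor genes were skipped. Results for some single genes are not reported here.

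The alternatives tried were a −log10 q of at least 5, lists of equal length, an overlap of 50% of the shorter peak, summits within 250 bp, merging of peaks within 100 bp, autosomes alone, gene-end windows of 500 and 2500 bp, loci with 50000 bp on either side, unmatched random lists, and fold enrichment or pileup in place of −log10 q. The calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. They were tested on simulated lists made from the 118441 control day 1 peaks. A difference between shared and gained peaks of 40 percentage points was recovered as 40.1, a presence of 60% as 59.9%, and a list whose locus peaks were thinned to 20% as 20.0% of 105 peaks.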

Results

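Open chromatin was profiled by ATAC-seq, which cuts and tags accessible DNA with a transposase, in mouse oligodendrocyte progenitor cells, the cells that give rise to the myelin-forming oligodendrocytes of the brain. The cells were immunopanned from the cortices of pups of postnatal day 4 to 7. There were 3 libraries, 1 per group. The groups were control cells at the progenitor stage, control cells after 1 day of triiodothyronine (T3, 60 nM), the thyroid hormone that starts differentiation in culture, and cells with a conditional knockout of Seh1 (Seh1cKO) after the same 1 day of T3. Seh1, encoded by Seh1l, is a component of the nuclear pore complex. The series title places it with Olig2, a transcription factor of the oligodendrocyte lineage, and Brd7, a subunit of the chromatin remodelling complex PBAF. The progenitor library held 23403600 fragments and 108788 peaks, the control day 1 library 18260883 fragments and 118441 peaks, and the Seh1cKO library 10845533 fragments and 46113 peaks. The Seh1cKO library therefore had 59.4% of the fragments of the control day 1 library and 38.9% of its peaks. With 1 library per group no difference below has a replicate check, and no p-value is given. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only.

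The 3 genes named by the study had called peaks in every library. At Seh1l (chromosome 18, 67774876 to 67795487, mm10) a peak covered the lower-coordinate end of the gene in all 3 libraries, with a −log10 q of 52.9 in progenitors, 40.8 in control cells at day 1 and 30.2 in Seh1cKO cells. A peak there does not check the knockout, because the deleted part of the gene is not given in the sources used here. At Brd7 (chromosome 8, 88329894 to 88362252) a peak at the higher-coordinate end was called in all 3 libraries, and the locus held 2, 2 and 1 peaks. Olig2 (chromosome 16, 91225550 to 91228677) had 5, 5 and 4 peaks. A peak at its lower-coordinate end spanned 91224667 to 91225779 in control cells at day 1 and 91224935 to 91225782 in Seh1cKO cells, and in progenitors a narrower peak lay at 91225096 to 91225451. The pileup of this progenitor peak was 88 fragments against 84 in control cells at day 1, and its fold enrichment was 2.40 against 6.04. Its smaller width is therefore no sign of less signal by itself. The strongest Olig2 peak of the progenitor library, 925 bp within the gene at 91226416 to 91227340 with a pileup of 205 fragments and a −log10 q of 78.2, overlapped no peak of either day 1 library. Whether its fragments come from the genome or from other DNA carrying Olig2 sequence was not tested and cannot be read from a peak table.

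**Figure D1:**
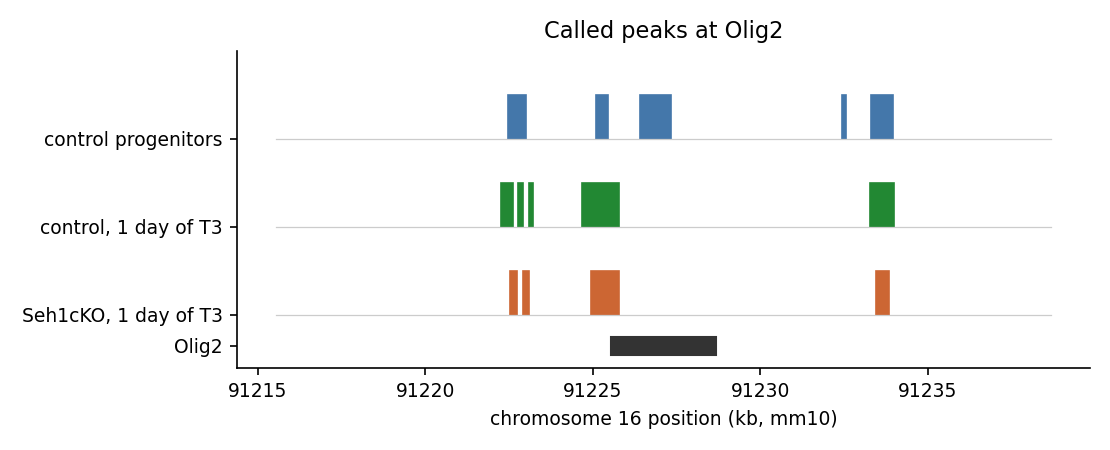
Called peaks (blocks, to scale, block height without meaning) at Olig2 and 10000 bp on either side in the 3 libraries, along chromosome 16 in kb of mm10. The block inside the gene from 91226416 to 91227340 is seen in the progenitor library only.

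The first comparison, between control progenitors and control cells after 1 day of T3, asks how open chromatin changes as differentiation begins. Strong peaks were almost all common to both stages. Of the strongest decile of day 1 peaks 98.4% overlapped a progenitor peak, and of the strongest decile of progenitor peaks 99.9% overlapped a day 1 peak. Weak peaks were mostly found in 1 library alone: over all peaks 39.7% (interval 39.4 to 40.0) of day 1 peaks and 43.5% (43.2 to 43.8) of progenitor peaks had a counterpart. With the 46113 strongest peaks of each list the first share was 69.5%. Among peaks with a −log10 q of at least 10, 3833 day 1 peaks (11.6% of 33050) and 940 progenitor peaks (3.50% of 26832) had no counterpart at the other stage, although the progenitor library was the deeper of the pair. The median fold enrichment of called peaks was 4.28 at day 1 and 3.91 in progenitors. With 1 library per stage, a difference in signal over background between libraries cannot be told apart from the stage.

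The examples of strong peaks gained at day 1 that follow are outside the rule for named genes and were chosen after their values were seen. Gained peaks also called in Seh1cKO cells included those within Mme (chromosome 3, 63326400 to 63326780, −log10 q 72.4), which encodes the membrane peptidase neprilysin, within the receptor kinase gene Mertk (chromosome 2, 128716496 to 128717046, 63.4) and within Ppargc1a (chromosome 5, 51830339 to 51830858, 60.0), a transcriptional coactivator of mitochondrial genes. Another lay 17866 bp from Tcf7l2, a transcription factor of newly formed oligodendrocytes (chromosome 19, 55951525 to 55951958, 48.3). The strongest that neither other library called included peaks within Sorcs1 (chromosome 19, 50545743 to 50546141, 64.8), Ptprk (chromosome 10, 28376792 to 28377184, 63.8), the retinoic acid receptor gene Rarb (chromosome 14, 16815804 to 16816089, 59.3) and the neuregulin receptor gene Erbb4 (chromosome 1, 68339049 to 68339540, 56.6).

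Peaks at the ends of protein-coding genes were shared between stages more often than distal peaks. A peak lay within 1000 bp of an annotated gene end at 13666 of 21887 genes in progenitors (62.4%) and 13841 at day 1 (63.2%), and 12633 genes had one at both stages. The rule for named genes took the 8 genes with the strongest gene-end peak in one library and none in the other, in each direction. For 15 of these 16 genes, among them Aktip, Kcnh6 and Emp3 for progenitors and Tsga10, Lig1 and Polg for day 1, a peak of the other stage overlapped the same site without reaching the window. The exception was Pqlc3, a transmembrane protein gene with a day 1 peak (chromosome 12, 16999732 to 17000405, −log10 q 40.4) that overlapped no progenitor peak and was overlapped in Seh1cKO cells. These strongest genes do not stand for the rest. Of 1033 genes with a gene-end peak in progenitors alone, at least 833 had a peak that overlapped none at day 1. Of 1208 with one at day 1 alone, at least 992 had a peak that overlapped none in progenitors. In the whole locus (gene and 10000 bp on either side) the largest differences with fewer peaks at day 1 were at Rbfox1 (74 in progenitors and 53 at day 1), Tshz2 (34 and 14) and Zfp993 (30 and 12), and those with more were at Ptprd (55 and 94), Cadm2 (40 and 67) and Pcdh15 (32 and 54). Many of these were calls of 1 library. Progenitors shared 18 of 53 day 1 peaks at Rbfox1, 7 of 14 at Tshz2 and 3 of 12 at Zfp993. The counts were 22 of 94 at Ptprd, 22 of 67 at Cadm2 and 10 of 54 at Pcdh15.

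More myelin genes had a gene-end peak at day 1 than in progenitors. Of 30 myelin and mature oligodendrocyte genes 20 had such a peak in progenitors and 26 at day 1. Genes with a peak called at day 1 and not in progenitors included Mog, a myelin surface glycoprotein gene (−log10 q 10.4), Enpp6 (10.3), Mal (8.63), Aspa, which encodes the enzyme that cleaves N-acetylaspartate (6.84), the connexin gene Gjb1 (2.90) and Tmem125 (2.90), and the reverse held for Ermn alone (2.61 in progenitors). Mog, Mal, Tmem125 and Ermn, and Cnp, Ugt8a and Pdgfra further on, are outside the rule and were singled out after their values were seen. The share of day 1 myelin gene ends also found in progenitors, 73.1%, lay at percentile 0.94 of 10000 random gene lists matched on peak strength. Mag, the gene of another myelin glycoprotein, had no locus peak in progenitors and 4 at day 1, and Mbp, the myelin basic protein gene, had 14 and 17. Other loci had fewer at day 1, as Aspa (5 and 2), Mal (4 and 2) and Cnp (7 and 5), and the myelin loci together held 171 and 182. Of the day 1 locus peaks 53.3% were also called in progenitors, against a median of 47.2% for random lists (percentile 93.4), but the share was −0.90 points from that expected from the strength of the peaks (percentile 13.7).

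**Figure D2:**
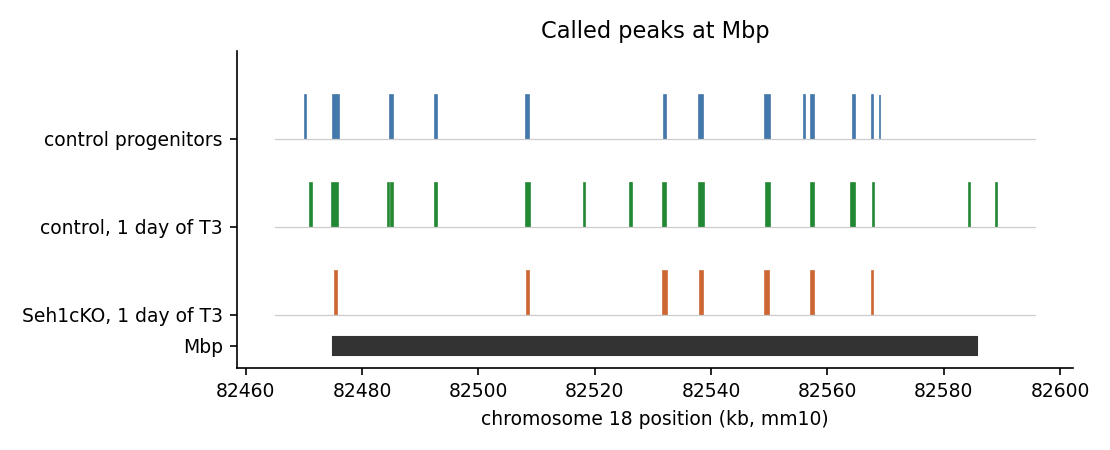
Called peaks (blocks, to scale, block height without meaning) at Mbp and 10000 bp on either side in the 3 libraries, along chromosome 18 in kb of mm10. There are 14 peaks in control progenitors, 17 in control cells at day 1 and 7 in Seh1cKO cells at day 1.

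In each of the other gene groups the number of genes with a gene-end peak differed by at most 2 between the stages. Peaks were found at 28 and 29 of 30 lineage regulators, 29 and 29 of 30 progenitor genes, 26 and 27 of 29 cell cycle genes, 25 and 24 of 25 sterol synthesis genes, 18 and 19 of 20 thyroid hormone response genes, 28 and 27 of 30 nucleoporin genes, 24 and 24 of 25 SWI/SNF genes and 24 and 26 of 26 housekeeping genes. Of the markers of other cell types, astrocyte genes had 16 and 16 of 20, neuron genes 19 and 21 of 24, microglia and macrophage genes 9 and 7 of 22, and endothelial and mural genes 9 and 11 of 24. Of the 11 endothelial and mural gene ends at day 1, 6 were also found in progenitors (54.5%, percentile 1.05 of matched random lists). Over whole loci the shares lay furthest above the median of random lists at cell cycle genes, where 67.2% of day 1 peaks were also called in progenitors against 50.2%, and at progenitor genes (55.0% against 43.8%), though with lists of equal length neither lay beyond the outer 2.5% of random lists. The cell cycle list also left it at a −log10 q of at least 5. The progenitor list also left it with loci of 50000 bp on either side and with unmatched random lists. The lowest share was at endothelial and mural genes (30.3% against 51.3%, percentile under 0.1), but this list left the outer 2.5% of random lists once the strength of its peaks was allowed for (percentile 6.3).

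The second comparison, between control and Seh1cKO cells after 1 day of T3, asks what open chromatin differs when Seh1 is deleted. Most strong control peaks were present in Seh1cKO cells and weak ones were not. Of the strongest decile of control day 1 peaks 96.3% overlapped a Seh1cKO peak, falling to 80.3% in the next decile and 1.02% in the weakest. Over all peaks the share was 31.3% (interval 31.0 to 31.6), and in reverse 81.4% (81.1 to 81.8) of Seh1cKO peaks overlapped a control day 1 peak. The value depends on list length: with the 46113 strongest peaks of each list 67.6% of control day 1 peaks were present in Seh1cKO cells, close to the 69.5% present in progenitors. When control day 1 pileups and local backgrounds were thinned at random to the Seh1cKO depth, 88392 control peaks remained callable on average, 1.92 times the number called in Seh1cKO cells. This is an upper limit, since the minimum length of a peak was not applied. Counting only thinned peaks with the p of Seh1cKO peaks of a −log10 q of at least 10, there were 21797 against 15607, or 1.40 times.

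**Figure D3:**
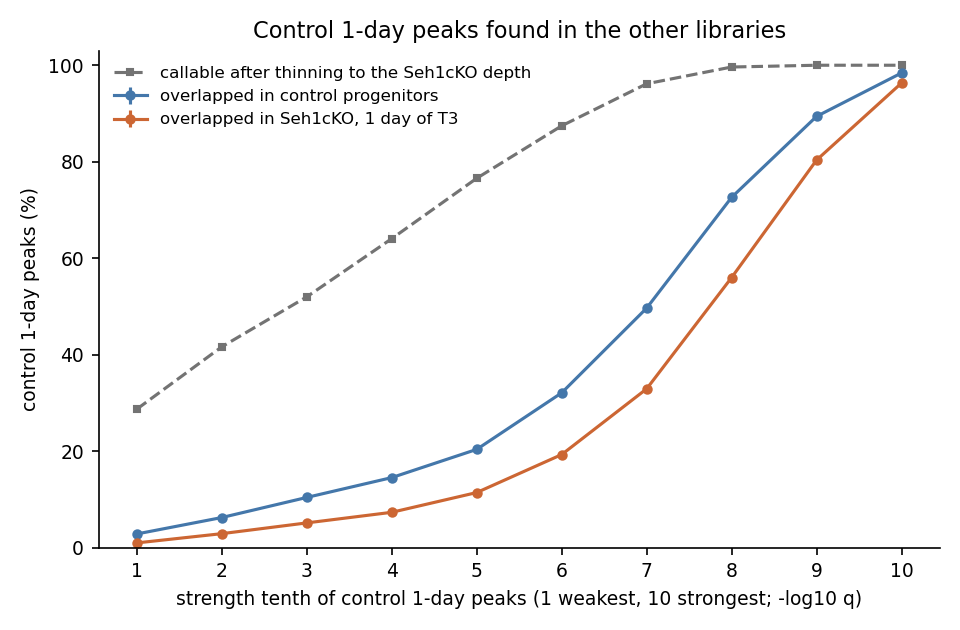
Share of control day 1 peaks (y axis, %) overlapped by a peak of control progenitors or of Seh1cKO cells at day 1, by strength decile of the control peak (x axis). Bars are exact 95% intervals, and the dashed line is the mean share still callable after thinning to the Seh1cKO depth. In the strongest decile the overlapped shares are 98.4% and 96.3%.

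Control day 1 peaks that progenitors lacked were present in Seh1cKO cells far less often than control day 1 peaks that progenitors shared. In the strongest decile 57 of 190 gained peaks (30.0%, interval 23.6 to 37.1) and 11351 of 11655 shared peaks (97.4%, 97.1 to 97.7) overlapped a Seh1cKO peak. In the next decile the shares were 26.0% of 1256 and 86.8% of 10588. With all 10 deciles weighted equally the shared peaks exceeded the gained peaks by 36.9 percentage points. Both classes rest on the same control day 1 library, so a difference arises even where no site changed. In the 8 weaker deciles the difference was 30.1 points, and 10 simulations without any changed site gave 32.3 there (median, range 31.0 to 34.5). The levels were far apart, with 7.04% of gained and 37.1% of shared peaks present against 34.9% and 67.3% in the simulations, so the simulations do not settle these deciles. The 2 strongest deciles together gave 64.1 points over 1446 gained peaks, where the simulations made at most 2 gained peaks. The simulations let libraries differ in depth and counting error alone. They held no duplicates and no difference in signal over background, so they do not settle the strongest 2 deciles either. The deciles were divided in this way after the values were seen. Of 1208 genes with a gene-end peak gained at day 1, 201 had one in Seh1cKO cells (16.6%, 14.6 to 18.9), and of 12633 genes with one at both stages 93.8%. These 2 classes were not matched on strength, and their median −log10 q was 3.61 and 32.3.

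**Figure D4:**
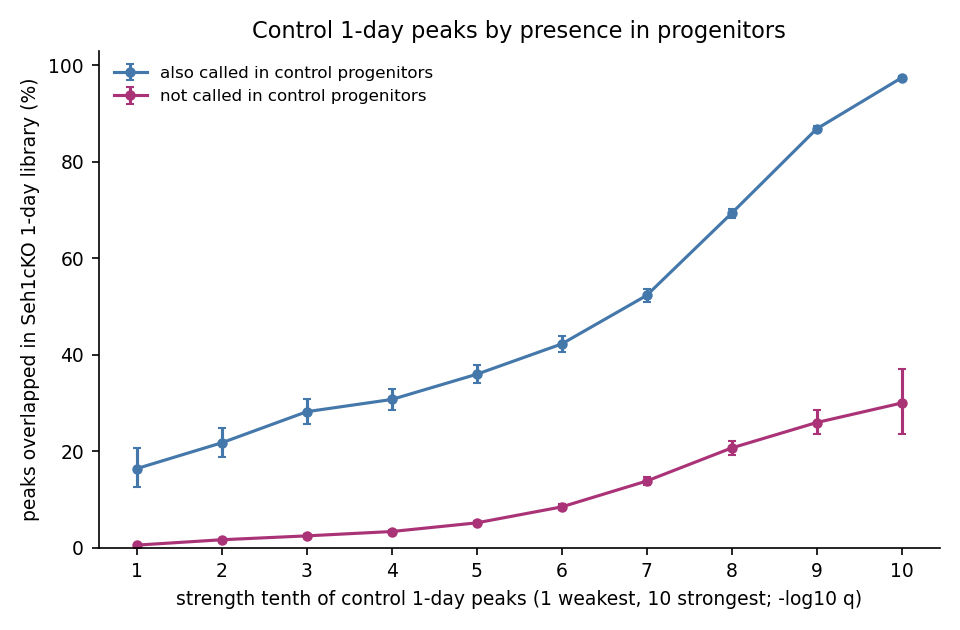
Share of control day 1 peaks overlapped by a Seh1cKO peak (y axis, %) by strength decile of the control peak (x axis), for peaks also called in control progenitors and for peaks not called there. Bars are exact 95% intervals. In the strongest decile the shares are 97.4% and 30.0%.

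The Seh1cKO list itself was mostly made of peaks common to both control stages. Of 46113 Seh1cKO peaks 72.5% overlapped peaks of both control libraries, 4099 a day 1 peak only, 2817 a progenitor peak only, and 5745 neither. With a −log10 q of at least 5 in every list 1417 overlapped a day 1 peak only and 879 a progenitor peak only. With lists of equal length the counts shared with a single stage were 4036 for day 1 and 4134 for progenitors. Among peaks called with a −log10 q of at least 10 in a single control library, Seh1cKO cells had 41.8% (38.6 to 45.0) of the 940 progenitor peaks and 23.7% (22.3 to 25.0) of the 3833 day 1 peaks. At −log10 q of at least 5 these shares were 17.3% (16.4 to 18.1) and 14.4% (13.9 to 14.9). The progenitor library was the deeper, and no value without change was computed for these shares.

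Among gene groups, myelin genes and markers of neurons, of microglia and macrophages and of endothelial and mural cells had the lowest shares of control day 1 gene-end peaks also found in Seh1cKO cells, none beyond the outer 2.5% of matched random lists. Of the 26 myelin genes with a control day 1 peak 18 had one in Seh1cKO cells (69.2%, percentile 3.5 of matched random lists), where thinning to the Seh1cKO depth left 24.8 on average. Thinned counts are upper limits. Over all control day 1 peaks thinning left 74.6% callable where 31.3% were present, so a shortfall against it is not particular to a list. Of the 8 without, 7 also had none in progenitors, among them Mog, Enpp6, Mal, Aspa, Gjb1 and Tmem125. Thinning left 6.2 of those 7, against which stands the 16.6% found for all gained gene ends. Gene-end peaks were called in all 3 libraries at Mbp, Cnp, Ugt8a and Bcas1. Of the control day 1 locus peaks, Seh1cKO cells had 7 of 17 at Mbp, all 7 overlapping the gene, 9 of 24 at Nfasc, 3 of 11 at Enpp6 and 4 of 15 at Bcas1. Of 21 neuron marker genes with a control day 1 peak 14 had one in Seh1cKO cells (percentile 23.0), where thinning left 19.4. For microglia and macrophage markers the count was 4 of 7 and for endothelial and mural markers 7 of 11.

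In the other groups nearly all genes with a control day 1 gene-end peak had one in Seh1cKO cells. These were 28 of 29 lineage regulators, 29 of 29 progenitor genes, 27 of 27 cell cycle genes, 23 of 24 sterol synthesis genes, 17 of 19 thyroid hormone response genes, 26 of 27 nucleoporin genes, 24 of 24 SWI/SNF genes, 15 of 16 astrocyte markers and 24 of 26 housekeeping genes. At Pdgfra and Cspg4, receptor and proteoglycan markers of progenitors, 3 of 5 and 4 of 10 control day 1 locus peaks were present. The number of Pdgfra locus peaks was nevertheless the same in both day 1 libraries. A peak at the lower-coordinate end of Pdgfra was called in progenitors (−log10 q 8.95) and Seh1cKO cells (3.03), and not in control cells at day 1. Over whole loci the cell cycle genes stood apart, with 56.2% of control day 1 peaks present against a random median of 41.7%. Endothelial and mural loci were at the other end, with 30.3% against 43.2% (percentile 0.65), but they were 6.39 points above the share expected from the strength of their peaks. For myelin loci the share was 42.9% against 37.9%, a difference that turned with the setting: it was −4.16 points with lists of equal length and −2.34 points against the share expected from the strength of the peaks.

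**Figure D5:**
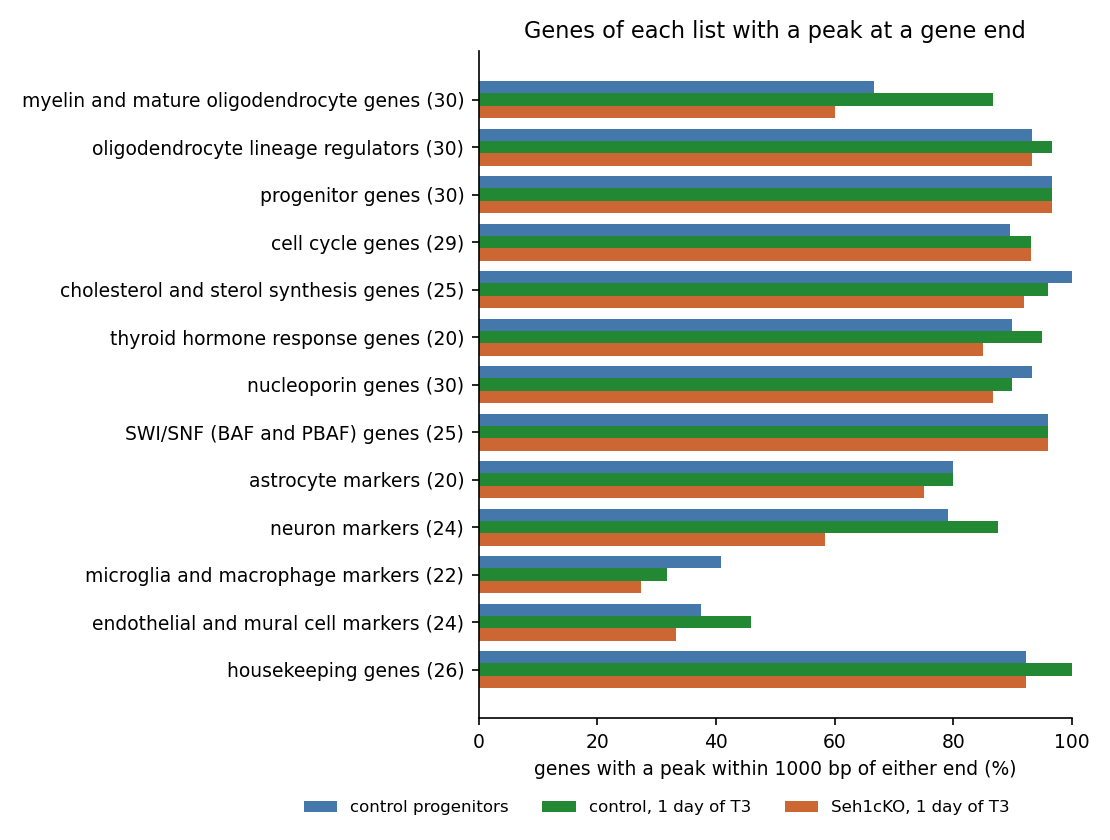
Share of the genes of each list (x axis, %) with a peak within 1000 bp of either gene end in each of the 3 libraries; the number of genes is in brackets. Bars are single libraries with no error. Myelin genes are at 20, 26 and 18 of 30.

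The 8 strongest genes in each direction of the second comparison were again mostly window effects, unlike the genes with such a difference as a whole. Of 1789 genes with a gene-end peak in control cells at day 1 and none in Seh1cKO cells, at least 1511 had a peak without overlap. In reverse the count was at least 191 of 245. Gene-end peaks were found at 12297 genes in Seh1cKO cells (56.2%). Of the 8 genes with the strongest control day 1 gene-end peak and none in Seh1cKO cells, 7 (among them Mrpl18, Dnajc1, Zbtb7a and Kdm6a) had an overlapping Seh1cKO peak outside the window. The exception was Iqcf6 (chromosome 9, 106627780 to 106628287, −log10 q 74.2 in control cells at day 1), whose peak progenitors shared. In the reverse direction 7 of 8 genes (among them Aktip, Mtfp1 and Pttg1) had an overlapping control day 1 peak, and the exception was Eif2s3y on chromosome Y. By a rule set after these values were seen, the strongest control gene-end peaks with no overlapping Seh1cKO peak followed at Fuz (48.0), a planar polarity and cilia gene, Dusp9 on chromosome X (43.0), Cdhr4 (42.1), Enpp3 (38.4) and Hes3 (38.3), and each of these 5 was shared with progenitors. In a list with 38.9% as many peaks, the largest differences in locus peaks were at the long genes Macrod2 (92 in control and 21 in Seh1cKO cells), Ptprd (94 and 23), Lsamp (85 and 21), Gpc5 (75 and 15) and Dmd (65 and 9). Few loci had more peaks in Seh1cKO cells, led by Clcn4 (2 and 5), Adamts4 (3 and 6) and Cdhr3 (4 and 7). Peaks near a gene end were present in Seh1cKO cells more often than distal peaks, at 43.2% against 29.1% with deciles weighted equally, and the same gap was seen between control stages (52.9% against 37.9%).

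The libraries also differed in the sex chromosomes. Seh1cKO cells had gene-end peaks at Eif2s3y (chromosome Y, 1010264 to 1010623, −log10 q 17.0), Uty (14.0) and Ddx3y (13.0), single-copy genes of the male-specific part of the Y chromosome, and neither control library had one there. Xist, the RNA gene that silences an X chromosome in female cells, had 5 locus peaks in progenitors, 3 in control cells at day 1 and none in Seh1cKO cells. Their −log10 q was 2.00 to 9.95 in progenitors and 2.42 to 6.15 at day 1. In the deciles of the day 1 values 5.17% to 32.9% of control day 1 peaks were present in Seh1cKO cells. The absence of Xist peaks there is therefore no sign of sex by itself. Chromosome X held 2.14% (2.01 to 2.27) of the Seh1cKO peaks on autosomes and X, against 2.95% in both control libraries. Among the 15607 strongest peaks of each list the X shares were 2.36%, 2.22% and 2.36%. Values of X-linked genes such as Gjb1, Kdm6a and Dusp9 are therefore read across libraries that differed in sex chromosome signal as well as genotype.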

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

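Both tests in this part were chosen after the result was seen. A signal outside the comparisons was found on chromosome Y, where 17 Seh1cKO peaks lay before 90 Mb against 1 peak in control progenitors and 3 in control cells at day 1. Repeats or mapping noise on the Y chromosome are argued against by the single-copy genes, since 3 of 8 Y genes examined (Eif2s3y, Uty and Ddx3y, not Kdm5d, Usp9y, Zfy1, Zfy2 or Sry) had a Seh1cKO peak at a gene end and none had one in a control library. A candidate explanation is that male animals contributed to the Seh1cKO culture and none detectable to the control cultures. Scaled by depth, the Seh1cKO pileups at these 3 genes would give at least 30.3 fragments in a control library, where pileups of 8 or 9 were enough for a call. The X chromosome does not decide the matter, because its share of all Seh1cKO peaks (2.14%) was below the 2.76% of control day 1 peaks callable at that depth, but the shares were alike among the strongest peaks of each list. Genotype and sex of the animals cannot be separated with 1 library per group, and a small share of male cells in the control cultures stays open.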

How the results depend on the processing

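Alternatives with the strongest 2 deciles, with other thresholds for peaks of a single control library, with the overlap of gene-end peaks and with shares expected from peak strength were chosen after the data were seen. In order, the values below are the share of control day 1 peaks in progenitors (39.7%), their share in Seh1cKO cells (31.3%), the excess of shared over gained peaks in Seh1cKO cells (36.9 points) and that of gene-end over distal peaks (14.1 points). With a −log10 q of at least 5 they were 60.1%, 43.4%, 44.9 and 21.2, and the lists held 44635, 56083 and 26069 peaks. With lists of equal length they were 69.5%, 67.6%, 46.6 and 19.7. With 50% overlap they were 36.7%, 29.5%, 34.6 and 12.1, and with summits within 250 bp 38.2%, 30.3%, 31.0 and 11.8. Merging moved only the last (13.2), as did a gene-end window of 2500 bp (10.0). The third was 42.1 with deciles by fold enrichment and 64.1 in the strongest 2 deciles. No direction turned among these, but the first 2 are shares and cannot turn, and the third is positive even in simulations without change. The cause of the moves was not tested, except that the first pair of settings keep fewer peaks. Autosomes alone moved none of the 4 beyond its counting interval. The excess of progenitor-only over day-1-only peaks in Seh1cKO cells (18.1 points) was 2.85 at a −log10 q of at least 5, 44.8 at 20 or more, and 35.2 and 46.4 in the upper bins of depth-scaled pileup, the last on 8 progenitor peaks. Counts of genes with a gene-end peak stayed within 1.5 times in every setting, and the myelin shares stayed inside their wide intervals, 59.1% to 84.6% in Seh1cKO cells. Of the list values for whole loci 216 stayed within their counting interval and 17 moved. Among lists in the outer 2.5% of random lists 1 value turned: endothelial and mural genes in Seh1cKO cells were 6.39 points above the share expected from peak strength. Among the other lists 27 values changed sign, as at myelin loci in Seh1cKO cells (4.89 points, and −2.18 at a −log10 q of at least 5). The cell cycle list stayed in the outer 2.5% of random lists in Seh1cKO cells in all 9 alternatives. The planned motif and GC alternatives were not run, as no genome sequence was used. No paired analysis was possible because each group has 1 library, and none could be left out. Depth limits weak peaks most, since 28.8% of the weakest control decile stayed callable at the Seh1cKO depth.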

Other observations

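The strongest peaks found in Seh1cKO cells alone, apart from those on chromosome Y, lay 15158 bp from Pthlh, the gene of parathyroid hormone-like hormone (chromosome 6, 147236735 to 147236951, −log10 q 64.4), within Cpeb4 (chromosome 11, 31922589 to 31922851, 35.5) and within Pcca (chromosome 14, 122568960 to 122569115, 29.7). They were 217, 263 and 156 bp wide. Sites shared by progenitors and Seh1cKO cells and missing from control cells at day 1 numbered 2767 in the progenitor list, and included peaks within Trnt1 (37.9), Ss18, a SWI/SNF subunit gene (37.2), and Tiam1 (35.5), and a peak 10348 bp from Tspan2, a myelin-associated tetraspanin gene (28.2). The strongest of these sites by score, on chromosome 14 at 19418171 to 19418285, had a pileup of 1643 fragments and a fold enrichment of only 1.48. Progenitor peaks with no counterpart in either day 1 library numbered 58664, led by the 925 bp peak within Olig2, for which DNA other than the genome was not excluded. Its −log10 q of 78.2 was followed by 39.1 for a peak 14509 bp from Trib1 and 36.5 for a peak 54641 bp from Pappa2.

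Of the tests in the next paragraphs, those on thinned strong peaks, on the strongest decile, of all chromosomes and of autosomes, and on peaks called in a single control library were chosen after the result was seen. The Seh1cKO list was shorter than the control day 1 list. Lower sequencing depth as the whole cause is argued against by thinned control peaks with the p of strong Seh1cKO peaks, 1.40 times as many as the Seh1cKO peaks where depth alone gives 1. This value lay under a bound of 1.5 set before it was seen, and the bound was lowered to 1 afterwards, because random thinning already allows for depth. Depth as a part of the cause stays open. Library complexity, the share of duplicate fragments, which were kept, the signal over background of each library, and the genotype all stay open and were not tested.

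Control day 1 peaks missing from progenitors were also mostly missing from Seh1cKO cells. For strong peaks, lower sequencing depth is argued against by the strongest decile, where shared peaks exceeded gained peaks by 67.4 percentage points though all were callable after thinning. That decile holds 190 of the 71448 gained peaks. Most gained peaks lie in the 8 weaker deciles, where depth stays open. There the difference was 30.1 points, and simulations without any changed site gave 32.3 (median). In the strongest decile of autosomal peaks alone the excess of shared over gained peaks was 67.0 points, so it does not rest on peaks of the sex chromosomes. Few peaks lie on those chromosomes, so this value could hardly move, and a wider effect of the animals' sex was not tested. Chance calls equally frequent in any single library are argued against by strong peaks found in neither other library, 5.35 times as many in control day 1 as in the deeper progenitor library (2926 and 547), but a higher rate of single-library pileups in control day 1 stays open. The 2926 peaks are themselves part of the pattern to be explained. The ratio moved with the threshold, from 2.20 at a −log10 q of at least 5 to 33.4 at 20 or more. Other cell types in the control day 1 library cannot be told apart from the stage, because the highest of the 4 marker lists, endothelial and mural genes, reached percentile 94.2 on only 6 strong locus peaks. Of those, 1 was absent from progenitors. The astrocyte, microglia and macrophage, and neuron lists lay at percentiles 60.9, 33.5 and 11.2. An effect of the genotype on sites gained under T3 stays open, and the values differ in direction. Seh1cKO peaks shared with a single control stage lay more often with day 1 than with progenitors (4099 against 2817). With lists of equal length they lay about equally (4036 against 4134). The pools were unequal, with 71448 day 1 peaks absent from progenitors and 61431 progenitor peaks absent from day 1. At a −log10 q of at least 10 Seh1cKO cells had 41.8% of progenitor-only and 23.7% of day-1-only peaks. At 5 or more the shares were 17.3% and 14.4%. The progenitor library was the deeper, and no value without change was computed for these shares.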
